A study of Homo sapiens with 4 samples.

How the data were processed

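ChIP-seq libraries of BT549 cells were made from Fra-1, c-Jun and normal rabbit IgG immunoprecipitates and from input DNA, 1 library for each of the 4 groups. Per the labels' protocols, cells were fixed with formaldehyde and libraries followed standard Illumina procedures. The submitters' processing notes name CASAVA 1.8, Bowtie 0.12.9 and Partek 6.6 and the builds hg19 and GRCh37. Which tool did which step, and with which settings, is not given in the sources used here. The reads themselves were not used here.

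The authors deposited 4 tables with values and 4 lists with positions only. Per the file headers, the tables give for each region the counts of reads of a factor library and of its reference library, and the highest count of extended reads in a window. The authors also give that highest count in RPM, which is used here as the peak height. The deposited p-values are a Mann-Whitney p per region, for which the file headers do not say what was compared, and a p of the factor's reads against the reference. The highest p against the reference was 0.0391 for Fra-1 and 0.0412 for c-Jun. The deposited fold was checked to be the factor's reads plus 1 over the scaled reference reads plus 1, within 1% for all 12769 Fra-1 and all 16380 c-Jun regions. Per the file headers, the percent columns give how much of a region is covered by regions called in each library. A region's fold, p and height are the authors' and are used only to describe or rank regions within a list.

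The deposited table of the Fra-1 sample has IgG as its reference and that of the c-Jun sample has input. The tables listed under the IgG and input samples were found to hold 910 Fra-1 regions that overlap an IgG region and 548 c-Jun regions that overlap an input region, so regions of the IgG and input libraries on their own were not analysed here. The Fra-1 list against IgG is the Fra-1 table without those 910 regions, and the c-Jun list against input is the c-Jun table without those 548. For c-Jun against IgG and Fra-1 against input only positions were used, and whether those lists were made by the same rule was not tested directly, so absence of a given region from the c-Jun list against IgG can mean either no excess over IgG or overlap with an IgG region. Heights were taken from the tables, where 14343 of 14941 and 12434 of 12973 of those regions were found.

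Depth was recovered as extended reads over RPM for Fra-1 and c-Jun, and from the scaling constant in the authors' fold (1.05 for IgG, 0.848 for input) for the backgrounds. This takes the constant to be the ratio of depths. An interval of a share is a 95% Wilson interval, an interval of a read ratio is exact, and intervals of correlations and ratios of medians come from 1000 bootstrap draws over regions. Reads without molecular identifiers are not independent molecules, so all of these cover counting error only. A fold over 0 reference reads is given as a lower bound against 3 reads in that region, which leaves out the counting error of the factor's reads.

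The main regions of a factor are those of its list against IgG that overlap its list against input by at least 1 bp. Regions of different factors count as shared from 1 bp of overlap, and chance was measured by 100 seeded random placements of the Fra-1 regions within the observed span of each chromosome. Peak heights of shared regions were compared by Spearman's rho and Pearson's r on log10 values, pairing each Fra-1 region with its tallest overlapping c-Jun region, and 8 relations of heights and reads were computed in that family. A single-factor region is a main region that overlaps no region of the other factor in any list or table. Correlations over chromosomes used 100000 permutations, two-sided. With 1 library per group there is no replicate test between groups, and all p-values describe these libraries and not conditions. Coordinates are 1-based on hg19.

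Groups, tests and the alternatives planned were fixed before the data were examined. The rule for named sites, also fixed then, took the 10 shared sites with the highest enrichment over IgG in each factor, up to 5 of the strongest single-factor regions per factor, and named genes with a nearby region. For c-Jun the deposited fold is over input, so that ranking replaced the one over IgG. The gene table at hand is of GRCh38, a different build from that of the regions, and no sequence of hg19 was used. Distances to transcription start sites, the 25 planned gene lists, the 19 planned motifs and the named genes are therefore not reported here. The limit of 5 RPM, the limits of 2 kb and of fold, the height ranking in both factors, the height-ratio sites, the Mann-Whitney split, the background densities and the relations with input over chromosomes were chosen after the data were seen. Alternatives were other lists, other overlap rules, a stricter height, local placement, and all regions of both tables, which was planned for the share over background regions. Chosen after the data were seen were all regions of both tables for the other results, a common lowest height and chromosome Y left out.

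Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots used matplotlib 3.10.9. The overlap steps were tested on simulated regions of which 79.7% were made to overlap: 80.3% were found by 1 bp, 79.9% by the 50% rule and 79.8% by midpoints, over 5000 regions.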

Results

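Chromatin from BT549, an established human triple-negative breast cancer cell line, was immunoprecipitated with antibodies to Fra-1 and to c-Jun, which are members of the Fos and Jun families that pair to form the AP-1 transcription factor. A library made with normal rabbit IgG and a library of input DNA served as backgrounds. The question, as the series states it, was where both AP-1 components bind across the genome of these cells. There were 4 groups with 1 library each, so no value below has a replicate error, and each interval covers counting error or resampling of regions only. The Fra-1 library held about 26763279 reads and the c-Jun library about 45571849, as recovered from the authors' read counts and RPM values. The authors' scaling of the backgrounds corresponds to about 25402009 IgG reads and 53709495 input reads. Positions are on hg19 (GRCh37), and genes near the regions were not analysed here.

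Fra-1 and c-Jun occupied many short regions of the BT549 genome, and most of these were above both backgrounds. The authors' Fra-1 list held 11859 regions against IgG and 12973 against input, and their c-Jun list held 14941 against IgG and 15832 against input. Of the Fra-1 regions against IgG, 98.4% overlapped a region of the Fra-1 list against input, which left 11669 main Fra-1 regions. Of the c-Jun regions against IgG, 14199 of 14941 met the list against input and are the main c-Jun regions. The main regions of both factors had a median length of 419 bp. Their median peak height was 3.33 RPM for Fra-1 and 1.91 RPM for c-Jun, and their median fold in the authors' deposited tables was 5.51 over IgG for Fra-1 and 6.44 over input for c-Jun. The lowest called peak was 1.83 RPM (49 extended reads) for Fra-1 and 1.14 RPM (52 extended reads) for c-Jun, so shorter peaks could be called for c-Jun than for Fra-1.

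Most Fra-1 regions were also c-Jun regions. Of the 11669 Fra-1 regions, 9852 (84.4%, 95% Wilson interval 83.8 to 85.1) overlapped a c-Jun region, and 9777 of the 14199 c-Jun regions (68.9%, 68.1 to 69.6) overlapped a Fra-1 region. The shared fraction rose with peak height. It went from 61.9% in the shortest quintile of Fra-1 regions to 95.7% in the tallest, and from 29.0% in the shortest quintile of c-Jun regions to 98.6% in the tallest. When the Fra-1 regions were placed at random on their own chromosomes 100 times, a mean of 0.444% and at most 0.668% of them met a c-Jun region, and a mean of 0.372% and at most 0.549% of c-Jun regions were met. Placement within 100 kb of each region's own position gave means of 1.70% and 1.40%. No placement of either kind came as high as the observed shares. The placements take no account of where reads of any library gather. In shared Fra-1 regions the IgG library itself had 6.75 times the reads per kb that an even spread would give. Exceeding the placements therefore does not by itself show joint binding. The shares depended on where each library's threshold lay: with c-Jun held to the lowest Fra-1 height of 1.83 RPM, 59.7% of Fra-1 regions overlapped one of the remaining 7574 c-Jun regions, and 90.4% of those overlapped a Fra-1 region.

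**Figure D1:**
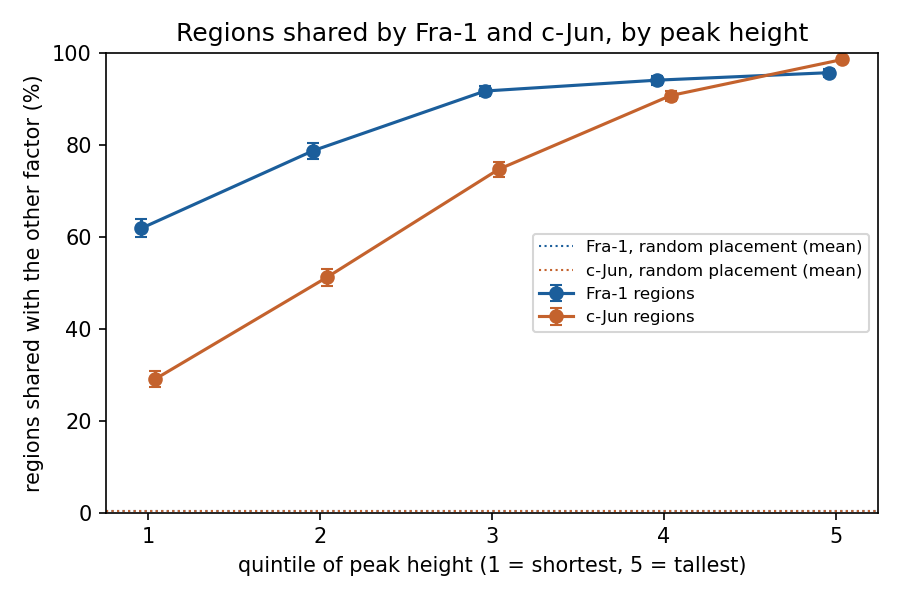
Share of regions that overlapped a region of the other factor (vertical axis, percent) in each quintile of peak height (horizontal axis), for Fra-1 (blue) and c-Jun (orange), with 95% Wilson intervals and the mean of 100 random placements as dotted lines. The Fra-1 share rises from 61.9% to 95.7% and the c-Jun share from 29.0% to 98.6%, while both placement means lie under 1%.

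Regions with a tall Fra-1 peak tended to have a tall c-Jun peak. Across the 9852 Fra-1 regions shared with c-Jun, Spearman's rho between the peak heights was 0.741 (95% bootstrap interval 0.731 to 0.751), and Pearson's r on log10 heights was 0.774. The median c-Jun height rose from 1.59 RPM in the lowest decile of shared regions by Fra-1 height to 5.31 RPM in the highest. The Fra-1 peak was a median of 1.58 times as high as the c-Jun peak in RPM. No shared region had a height ratio more than 4 times above this median, and 13 had a ratio more than 4 times below it. Extreme ratios are cut off by definition, since a shared region needs a called peak of at least 1.83 RPM for Fra-1 and 1.14 RPM for c-Jun. Tall Fra-1 regions without a called c-Jun peak are not among these ratios. The lowest ratios, picked out after their values were seen, included chr17:27568482-27568698, with 1.87 RPM for Fra-1 beside 7.72 RPM for c-Jun, and chr1:16007662-16008062, with 2.20 beside 8.38 RPM. The c-Jun regions there were 925 and 948 bp long beside 217 and 401 bp for Fra-1, so the c-Jun maximum need not lie within the Fra-1 region. The highest ratio was at chr6:136316390-136316875, with 5.46 RPM for Fra-1 and 1.32 RPM for c-Jun. These relations are across regions of a pair of libraries, and neighbouring regions are not independent replicates. IgG and c-Jun reads per kb also had a rho of 0.514 in the shared regions, so a positive relation was not limited to the factor libraries.

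**Figure D2:**
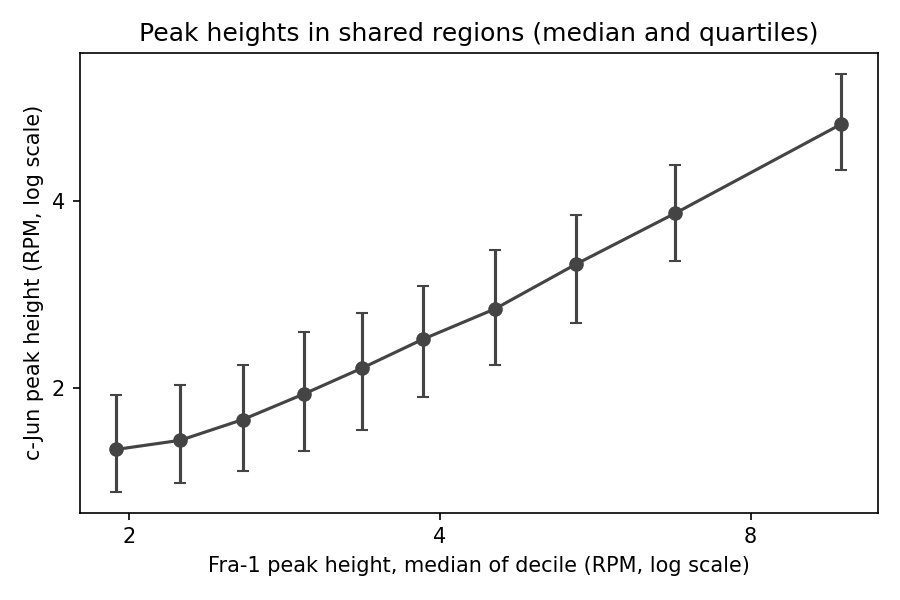
Median c-Jun peak height with quartiles (vertical axis, RPM, log scale) in deciles of Fra-1 peak height (horizontal axis, median of each decile in RPM, log scale) over the 9852 shared regions. The median c-Jun height increases from 1.59 to 5.31 RPM.

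At the shared sites with the highest c-Jun fold over input, the input library had no reads at all. The first was chr3:111529682-111530333, with 494 c-Jun reads against 0 input reads, at least 194-fold enriched when the input is set to 3 reads (exact lower limit 157, which also covers the counting error of the c-Jun reads). Fra-1 had 476 reads there against 44 IgG reads and a fold of 10.1 in the authors' deposited table. It was followed by chr3:84157461-84158334 (at least 189-fold), chr9:114505471-114506042 (at least 165-fold), chr2:157888483-157889080 (at least 145-fold) and chr17:39010380-39010937 (at least 132-fold). All of the first 10 sites had 0 input reads, and their c-Jun heights lay between 4.19 and 7.48 RPM. The Fra-1 heights were 3.40 RPM at chrX:119915187-119915757, below the median of 3.59 RPM of shared Fra-1 regions, and 5.60 RPM or more at the other 9. Of the 9777 shared c-Jun regions, 344 had 0 input reads. An even spread of the input library would give 18.0 reads per kb, so a ranking by fold picks sites that lack input, and the bounds cover counting error and not a gap in the input library.

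The shared sites with the highest Fra-1 fold over IgG were short peaks with little or no IgG signal. The first was chr6:90007677-90007998, with 68 Fra-1 reads against 0 IgG reads, at least 21.5-fold enriched over 3 reads (exact lower limit 17.0), and a height of 2.06 RPM. The next were chr3:124705070-124705358 (67 against 0 reads, at least 21.2-fold) and chrX:16178904-16179172 (66 against 0, at least 20.9-fold). At chr3:44927140-44927487 there were 104 Fra-1 reads and 1 IgG read, a ratio of 98.7 with an exact interval of 17.3 to 3936. The first 10 sites lay between 1.83 and 3.40 RPM, and 8 of them had no IgG read.

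Among the main regions, a ranking by height in both factors, made after the values were seen, began with chr9:124049174-124049816. Regions over IgG regions are not part of this ranking, and chr1:96828008-96828693 among them was taller in both factors, with 34.7 and 18.5 RPM. At chr9:124049174-124049816 the Fra-1 peak reached 30.5 RPM (989 reads against 65 for IgG, fold 14.2 in the authors' deposited table), and the c-Jun peak reached 10.8 RPM (644 reads against 103 for input, fold 7.30). At chr1:98403135-98404010 the heights were 20.8 and 9.98 RPM, and at chr8:117435935-117436999 they were 18.2 and 9.92 RPM. Further sites of this kind were chr1:178207757-178208637, with 17.7 and 9.76 RPM, and chr12:66050498-66051182, with 17.3 and 9.50 RPM.

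Regions of a single factor were mostly lower in height than the shared regions of the same factor. In no list of the other factor were 1707 Fra-1 regions (14.6%) and 4376 c-Jun regions (30.8%). The Fra-1-only regions had a median height of 2.24 RPM, against 3.59 RPM for shared Fra-1 regions, and the c-Jun-only regions 1.38 RPM against 2.35 RPM for shared c-Jun regions. The median fold in the authors' deposited tables went the other way for Fra-1, at 7.46 over IgG in Fra-1-only and 5.35 in shared regions, and was 3.98 over input in c-Jun-only and 7.55 in shared c-Jun regions. A height of 5 RPM, a limit set after the values were seen, was reached by 125 Fra-1-only and 9 c-Jun-only regions. Heights of the libraries are not on an equal footing, given the lowest called heights and the median ratio of 1.58 in shared regions, so these medians and counts were not compared between factors. With c-Jun held to the lowest Fra-1 height, the number of c-Jun-only regions fell to 704. In the upper part of each set, from its median height upwards, 289 Fra-1-only and 603 c-Jun-only regions remained.

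The tallest Fra-1-only regions were strongly enriched over IgG. The first was chr20:44816777-44817406, with a height of 15.8 RPM and 625 Fra-1 reads against 12 IgG reads, a ratio of 49.4 after scaling for depth (exact interval 28.1 to 96.2). Next came chr1:7905187-7905793 (10.8 RPM, 407 against 10 reads), chr1:33135726-33136306 (10.8 RPM, 375 against 21), chr4:103768832-103769419 (10.7 RPM, 407 against 6) and chr9:5822635-5823268 (10.5 RPM, 396 against 11). The tallest c-Jun-only region, chr10:3827219-3828005, reached 7.18 RPM with 545 c-Jun reads against 134 input reads, a ratio of 4.79 (3.96 to 5.83). It was followed by chr12:12715235-12715937 with 6.58 RPM (457 against 62 reads) and chr19:42772261-42772853 with 5.73 RPM (362 against 103).

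Background reads differed between shared and single-factor regions, and in opposite ways for Fra-1, whose background here is IgG, and c-Jun, whose background is input. The median IgG density was 57.4 reads per kb in Fra-1 regions shared with c-Jun and 26.4 in Fra-1-only regions, while an even spread of the IgG library over the chromosomes would give 8.50. In the tallest decile of Fra-1 regions the medians were 81.3 and 15.9 reads per kb. For c-Jun the order was the other way: c-Jun-only regions had a median of 74.8 input reads per kb and shared c-Jun regions 52.7, where an even spread would give 18.0. The c-Jun-only median was the higher in each of the 10 deciles of c-Jun height, although the upper 2 deciles held only 18 and 17 such regions. In the authors' deposited table, 1329 c-Jun main regions had a Mann-Whitney p above 0.05, of which 33.5% were shared with Fra-1, against 72.5% of the other c-Jun regions. Within the 7 deciles of height with at least 20 such regions, this difference averaged 13.6 percentage points, weighted by their number. For Fra-1 the 593 such regions were shared in 74.9% of cases against 84.9%, but within the 5 deciles of height with at least 20 such regions the difference averaged -6.87 points.

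**Figure D3:**
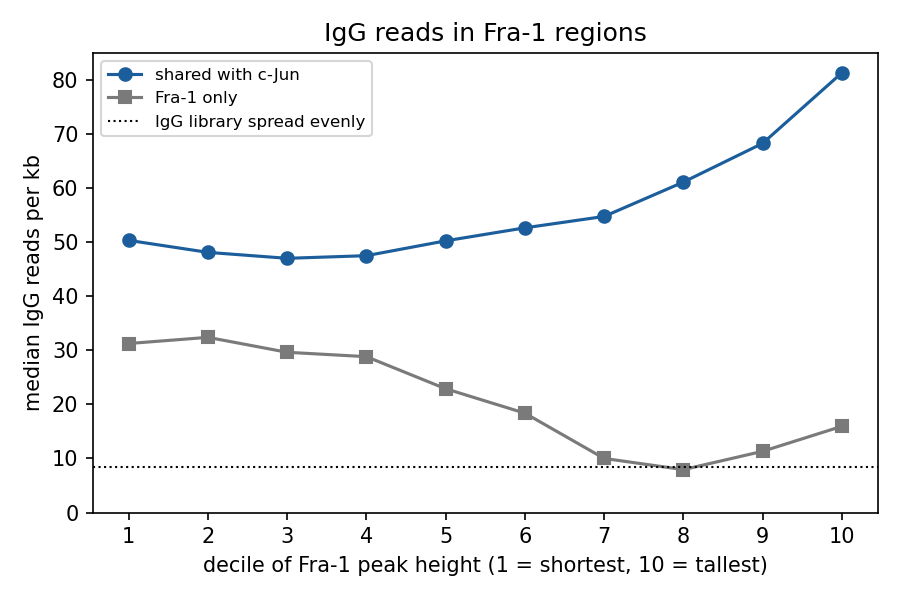
Median IgG reads per kb (vertical axis) in deciles of Fra-1 peak height (horizontal axis) for Fra-1 regions shared with c-Jun (blue circles) and Fra-1-only regions (grey squares), with the density of an evenly spread IgG library as a dotted line. In the tallest decile the medians are 81.3 and 15.9 reads per kb, and the dotted line lies at 8.50.

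The very tallest Fra-1 regions were largely missing from the Fra-1 list made against IgG. In the authors' deposited tables, 910 Fra-1 regions overlapped a region called in the IgG library, and these are the ones that list leaves out. Their median height was 9.85 RPM against 3.33 RPM for the main Fra-1 regions. The share of Fra-1 regions over an IgG region rose from 0.117% in the shortest quintile to 27.7% in the tallest, and of the 100 tallest Fra-1 regions 95 lay over an IgG region. This was so for 320 of the 500 tallest and 468 of the 1000 tallest. The Fra-1 list against input held 63 of the 100 tallest and 925 of the 1000 tallest. Most of the 910 were still enriched over IgG: 664 had a fold of 3 or more, all 664 lay over a c-Jun region, and 644 were in the Fra-1 list made against input. The tallest of them were chr1:96828008-96828693 (34.7 RPM, 1195 Fra-1 against 99 IgG reads, ratio 11.5, exact interval 9.33 to 14.2) and chr8:126231447-126232042 (34.5 RPM, 1125 against 124 reads, ratio 8.61, 7.15 to 10.5). Another 127 had a fold under 1.5, among them every Fra-1 region of 2 kb or more. The fold limits of this paragraph and the 2 kb limit were chosen after the values were seen.

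The c-Jun regions over input regions were of another kind. There were 548, with a median height of 3.77 RPM, a median of 260 c-Jun reads against 160 input reads, and a median fold of 1.70 in the authors' deposited table. Only 67 had a fold of 3 or more. The very tallest c-Jun regions were also largely missing from the lists: of the 100 tallest in the c-Jun table, 0 were in the list against IgG and 36 in the list against input. Of the 500 tallest these lists held 81 and 368, and of the 1000 tallest 361 and 833. In the main sets, 14 of the 11669 Fra-1 regions (95% Wilson interval 0.0715% to 0.201%) and 9 of the 14199 c-Jun regions (0.0634%) lay over one of these 910 or 548 regions. These shares are low largely by construction. The Fra-1 list against IgG leaves out the 910 and the c-Jun list against input the 548, so the shares do not measure background. IgG and input regions that meet no region of the tables are not known here.

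Many of the longest and highest read accumulations were nearly as deep in the backgrounds as in the factor libraries. At chr19:27731771-27740745 the Fra-1 library had 45966 reads and the IgG library 41705, a ratio of 1.05 after scaling. At chr7:61967146-61973681 they had 28808 and 26011 reads, also a ratio of 1.05. All 24 Fra-1 regions of 2 kb or more lay over an IgG region. Of the 52 c-Jun regions of 2 kb or more, 24 had a fold under 5 over input, all of them between 1.07 and 2.69, and all 24 lay over an input region.

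The other 28 long c-Jun regions stood far above input and were absent from the c-Jun list made against IgG. Their folds over input ran from 21.9 to 69.6, with 295254 c-Jun reads against 12613 input reads in all. The one with the most c-Jun reads was chr10:42381220-42397501, with 89124 c-Jun and 4790 input reads. By position, 14 of the 28 lay on chromosome 4, 6 on chromosome 10, 3 on chromosome 16, 3 on chromosome 2 and 2 on chromosome Y. Several were neighbouring stretches, such as chr4:49093245-49110882 and chr4:49110894-49113398, so the 28 are not as many separate sites. Of the 28, 5 lay over an input region. Next to the chromosome 10 region named above, chr10:42397624-42401274 had a fold of only 1.55. The Fra-1 list made against input met 26 of the 28. The Fra-1 table against IgG, which keeps regions over IgG regions, met only 2. Among regions under 2 kb, 1610 of the c-Jun list against input were absent from the list against IgG, with a median fold over input of 12.6. Of these, 1173 were met by the Fra-1 list against input, 65 by the Fra-1 list against IgG and 797 by the Fra-1 table.

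**Figure D4:**
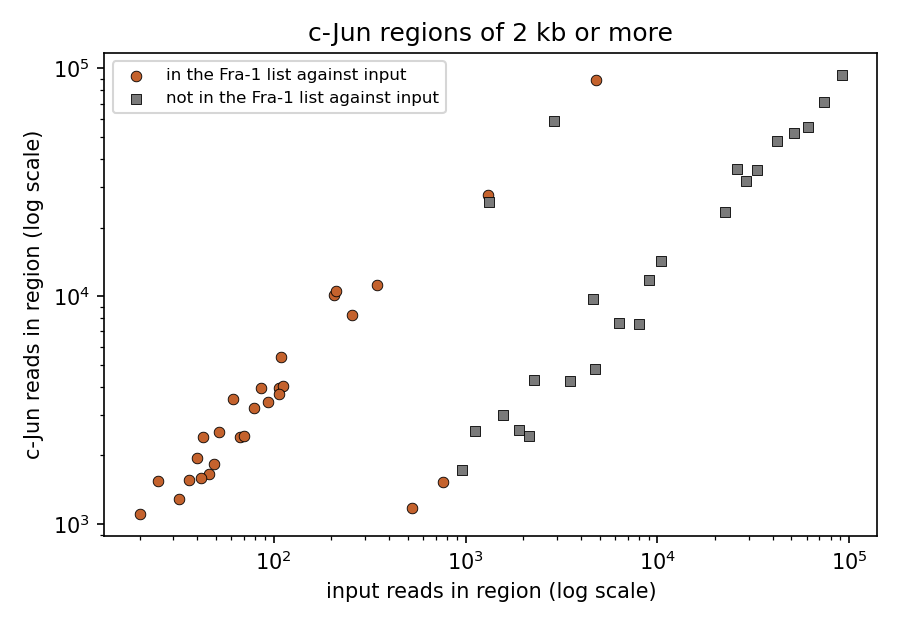
c-Jun reads (vertical axis, log scale) against input reads (horizontal axis, log scale) in the 52 c-Jun regions of 2 kb or more. Orange circles are regions met by the Fra-1 list against input and grey squares are the others. The 28 regions with folds of 21.9 or more form the upper left band, and 26 of them are orange.

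The density of regions ran in nearly the same order over the chromosomes for both factors. Per Mb, Fra-1 main regions were densest on chromosome 20 (5.83), chromosome 10 (5.45), chromosome 1 (4.97) and chromosome 8 (4.93). They were sparsest on chromosome X (2.17) among chromosomes 1 to 22 and X. The c-Jun main regions had 7.11 per Mb on chromosome 20, 6.47 on chromosome 10 and 2.57 on chromosome X. Over these 23 chromosomes the densities of both factors had a Spearman rho of 0.953 and a Pearson r of 0.976, each with a permutation p of 1e-05, the smallest that 100000 permutations give, and r was 0.968 without chromosomes 20 and 10. Between 78.2% (chromosome 16) and 87.2% (chromosome 6) of Fra-1 regions were shared with c-Jun, so the densities largely count the same regions. The relation follows in large part from that overlap, and its p is no separate evidence. Among these 23 chromosomes the share of Fra-1 regions over an IgG region was highest on chromosomes 8 (15.6%), 20 (11.5%), 9 (10.4%) and 1 (9.40%). On chromosome Y it was 13.3%, with only 15 Fra-1 regions. Input reads per kb in c-Jun regions also went with c-Jun region density (rho 0.622, permutation p 0.00224, Benjamini-Hochberg adjusted 0.00560 over 5 relations, and r 0.614, permutation p 0.00202), and r fell to 0.446 without chromosomes 20 and 17. With Fra-1 region density the relation was weaker (rho 0.468, permutation p 0.0250, adjusted 0.0250, and r 0.490, permutation p 0.0177). Its r fell to 0.312 without chromosomes 20 and 17.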

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

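The tests of IgG reads against Fra-1 occupancy, of copy number as the whole cause, of carry-over from the Fra-1 library, of input against IgG reads over chromosomes and of the lower tail of c-Jun heights were chosen after the data had been seen, and the test of IgG by Fra-1 height and that of the lower tail each replaced an earlier version with the same label after its value was known. The test against Fra-1 occupancy replaced one that compared IgG reads in shared and Fra-1-only regions at matched height (2.53 times, 2.15 to 3.17) and had counted for the explanation, although it restated the difference that had prompted it. The other tests were written before their values were computed.

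Regions left out of the deposited list for lying over a region of its own reference library had tall peaks. The 910 Fra-1 regions over IgG regions had a median height of 9.85 RPM and a median fold of 4.21 over IgG in the authors' deposited table. Of the 910, 765 were in the Fra-1 list against input. The 548 c-Jun regions over input regions had a median height of 3.77 RPM, above the 1.91 RPM of the main c-Jun regions, but a median fold over input of only 1.70 in the authors' deposited table.

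The IgG library had regions of its own where Fra-1 was strongest. In Fra-1 regions under 2 kb with a c-Jun partner, IgG reads per kb were 1.84 times as high in the upper as in the lower quintile of Fra-1 height and input reads 1.14 times, a quotient of 1.61 (1.49 to 1.74) where copy number as the whole cause would give a value near 1. As a contributor copy number cannot be told apart: the planned split by overlap with IgG regions, where the log input ratio was 0.433 of the log IgG ratio (0.344 to 0.525), spans the preset 0.5 and chose its groups by IgG reads. A carry-over of the Fra-1 library would put IgG reads into Fra-1-only regions as well. In the upper 4 deciles of height the shared regions had 5.75 times the IgG density of Fra-1-only regions (5.23 to 7.15). IgG reads that follow Fra-1 occupancy with or without c-Jun would give a positive rho between IgG and Fra-1 reads per kb. Over 1772 Fra-1 regions under 2 kb in no c-Jun list, this rho was -0.169 (-0.217 to -0.124). Both tests were chosen after the IgG reads of Fra-1-only regions had been seen, so neither value is independent evidence against these explanations. Whether the IgG reads come from the c-Jun library, from open chromatin or from another source stays open, and no biological explanation was tested.

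The 125 tall Fra-1-only regions had a median of 233 Fra-1 reads against 6 IgG reads, with no c-Jun region in any list. That they are the lower tail of the c-Jun heights of shared regions is argued against: of the 2886 shared Fra-1 regions of 5 RPM or more, 9 had a c-Jun height within 1.5 times the lowest called, or 0.072 per tall Fra-1-only region (0.0292 to 0.124), where such a tail would give at least 1. c-Jun reads in the 125 regions themselves were not read here, so a weak c-Jun signal under the threshold stays open. The planned ratio for low copy number cannot decide: the nearest shared regions within 1 Mb had 5.61 times their IgG density (4.53 to 6.95). Shared regions had 5.75 times that of Fra-1-only regions in the upper 4 deciles of height anyway. Those nearest regions had 65.8 IgG reads per kb beside 57.4 for all shared regions, so their segments were not low in IgG reads. The tall Fra-1-only regions themselves had a median of 11.5, and an even spread would give 8.50. Left open and untested are that Fra-1 may pair with another Jun protein at these sites, or that they may hold reads of a different library.

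Input reads in c-Jun regions varied far beyond counting error. Copy number as the whole cause is argued against, since over 245 bins of 10 Mb the input median ran from 6.62 to 149 reads per kb and the IgG median from 29.0 to 76.5, with a log2 slope of 0.11 (0.07 to 0.15) where copy number would give 1. A part played by copy number cannot be told apart: the planned neighbour rho of 0.389 (0.369 to 0.407) lies between the preset 0.2 and 0.5, and input and IgG reads per kb rose together over 23 chromosomes (rho 0.516, permutation p 0.0130, adjusted 0.0168 over 5 relations; r 0.552, p 0.00653, and r 0.478 without chromosomes 20 and 17), as copy number would have it. An uneven input library stays a candidate explanation that the planned measure cannot decide. In regions of 350 to 450 bp the variance over mean was 28.0 (23.7 to 33.4) after division by the neighbours and 18.3 before it. Both values restate the excess over counting error, and the division did not lower it. Base composition could not be tested without the sequence.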

How the results depend on the processing

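Of 61 alternative values, 43 kept their call, interval or approximate size and 18 moved, and none reversed. A number of regions counted as kept when it lay within 1.5 times the main number in either direction. A shared percentage counted as kept whenever no placement reached it, however far the percentage itself changed, so these values could hardly have moved. Placement within 100 kb repeats the main percentages against another set of placements. The count of 43 is therefore no measure of stability for the shares. The common lowest height, the removal of chromosome Y and, except for the shares over an IgG or input region, all regions of both tables were chosen after the data were seen. The shared percentages exceeded all 100 placements under every alternative run, although the common lowest height changed them most, to 59.7% for Fra-1 and 90.4% for c-Jun, and lowered the c-Jun regions to 7574. Spearman's rho of the heights became 0.774 with the lists against input, 0.681 from the median height upwards, 0.775 with all regions of both tables, 0.682 with the common lowest height, 0.775 with the 50% rule and 0.763 with midpoints within 100 bp, and the cause of these shifts was not tested. From the median height upwards there were 289 Fra-1-only and 603 c-Jun-only regions, and the common lowest height left 704 c-Jun-only regions. By construction, fewer regions enter these counts. Stricter overlap rules raised them: Fra-1-only regions went from 1707 to 2291 by the 50% rule and to 2517 by midpoints. The c-Jun-only regions went from 4376 to 4858 and 5081, and all of these values counted as kept. The share of Fra-1 regions over an IgG or input region was 0.843% with the lists against IgG, 6.13% with those against input, 7.91% in the whole table and 0.0428% by the 50% rule. For c-Jun it was 1.03%, 4.88%, 8.06% and 0.00704%. These shares count overlap with the 910 Fra-1 and 548 c-Jun regions that lie over IgG or input regions, not with the background regions themselves. The Fra-1 list against IgG holds no region over an IgG region, and the c-Jun list against input no region over an input region. The c-Jun table held 870 regions that met the 910, the c-Jun list against input 772 and the c-Jun list against IgG only 10. For Fra-1, 200 regions of the table met the 548, with 100 in the list against IgG and 31 in the list against input. The counts for c-Jun are those of a list against IgG that leaves out regions over IgG regions. A lack of c-Jun excess over IgG at these regions was not tested separately. The transcription start site, gene list and motif alternatives were not run, including shuffled sequences. No paired analysis was possible because each group had 1 library, and no library could be left out. Depth limits the weak peaks: the lowest called Fra-1 peak stood on 49 extended reads and the lowest c-Jun peak on 52, so a factor's absence at such heights was not detectable.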

Other observations

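The spacing and window measures of this part were chosen after the data had been seen.

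Shared Fra-1 and c-Jun regions lay close together along the genome. Of the 9852 shared regions, 39.3% had another within 10 kb, against a mean of 6.87% for random placement and 17.2% for placement within 100 kb of each region. The densest windows of 500 kb were at chr8:126226504-126677182 and chr14:61570223-62036938, each with 19 shared regions, followed by chr1:234630990-235117131 with 18. In 100 random placements the densest window of each held at most 13. Input was raised in these 3 windows, with medians of 105, 97.8 and 125 reads per kb beside 52.7 over all shared c-Jun regions, and the placements do not account for this. The window on chromosome 8 also held 4 Fra-1 regions over IgG regions, among them one of the tallest, at chr8:126231447-126232042 with 34.5 RPM. At chr4:169442920-169587997, 15 shared regions lay within 145 kb, with a median of 2.47 RPM for Fra-1 and 1.89 RPM for c-Jun.

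In the shared main regions, IgG reads went with c-Jun reads more closely than with Fra-1 reads. There Spearman's rho was 0.514 between IgG and c-Jun reads per kb and 0.358 between IgG and Fra-1 reads per kb. These Fra-1 regions were called against IgG and leave out the 910 over IgG regions, which restricts the relation of IgG and Fra-1 reads. The c-Jun reads were counted over the paired c-Jun region and came from a deeper library. The rhos are therefore not on an equal footing. In Fra-1-only regions the relation of IgG and Fra-1 reads had the opposite sign, at -0.234. IgG and input reads were only loosely related, at 0.160.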
